A study of Homo sapiens with 14 samples.

How the data were processed

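RNA was measured by sequencing in 14 human tendon biopsies, 7 of healthy hamstring tendon and 7 of rotator cuff tendon with chronic tendinopathy. Per the labels' protocols, RNA was extracted with a column kit for fibrous tissue that included a DNase step, and libraries were made with a NEBNext Ultra II RNA kit. The submitters' processing notes name cutadapt (version 2.3), FastQC (version 0.11.8), STAR (version 2.7.8a) and RSEM (version 1.3.3), and the builds hg38 and GRCm38. Those notes were used here without their roles or order, so which tool made the counts and whether strand was used were not given in the sources used here.

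The deposited table held whole-number counts per gene, with 60668 rows under versioned Ensembl identifiers and 1 column per sample, as the authors deposited it. No normalization was applied to these counts, as far as the deposited values show. A column was tied to a sample through the label that carried the same name. Gene symbols were found for 60340 rows. Positions on GRCh38 from GENCODE 29 were found for 58561 rows. Of the counts from 1 to 20, between 24.5% and 36.4% were odd numbers in each library. Mates of a read pair may therefore have been counted separately, which was not stated, so a fit on halved counts was added. Genes that share reads with near-identical copies or overlap another gene carry uncertain counts, because the handling of such reads was not given in the sources used here. CD68 was among the genes left out by the filter on low counts.

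Total counts per library ranged from 16171745 to 59883154. Groups were taken from the genotype label of each sample, and replicates were numbered in accession order, so the numbers pair nothing. All samples carried the same batch label. The labels did not state that the samples came from separate donors, so the p-values measure only the spread between these samples. Rows for genes linked to donor sex (556 rows) were left out of every test. Every pair of libraries was compared by a chi-square over genes with at least 50 counts in the pair. The closest pair, tendinopathy 1 and 7, had a chi-square of 19.0 per degree of freedom, above sampling noise. That spread does not show whether a pair came from separate donors, so all 14 libraries were kept as the labels list them.

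Counts were analysed in R 4.3.3. Genes were filtered with filterByExpr by group, which left 17546 genes, and scaled by TMM. The quasi-likelihood F test of edgeR 4.0.16 compared tendinopathy with healthy, with the group as the only term and Benjamini-Hochberg adjustment over all genes tested. The threshold was an adjusted p of 0.05. A log2 fold change was tendinopathy minus healthy. Log2 CPM values used a prior count of 2. The SE of a log2 fold change was its size divided by the square root of F. Of 50 gene lists fixed before the data were examined, the 49 with at least 5 tested members were tested with camera (limma 3.58.1) on voom values. The inter-gene correlation was preset at 0.01, and p-values were adjusted over the lists. An estimated correlation and fry served as alternatives.

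The rule for named genes, fixed before the data were examined, took the 7 AMPK subunit genes and up to 8 genes per direction. Those had to pass the threshold with a mean log2 CPM of at least 1 and no overlap between the groups. It also took the 3 members with the smallest adjusted p from each list that passed or that had at least 0.25 of its members called, and from the lists of AMPK regulators and substrates. PITX1, TBX4, TBX5, SCX, MKX, TNMD, COL1A1 and COL3A1 were always named. Sex-linked genes, immunoglobulin and T cell receptor segments and rows without a symbol were excluded. Some genes that the rule takes are not reported here.

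Alternatives fixed beforehand were RLE and upper-quartile scaling, no filter and a filter of 1 CPM in at least 7 samples, and DESeq2 1.42.0. The others were limma-voom with and without sample weights, counts thinned to the smallest library, library sizes without mitochondrial and the top 10 genes, 1 surrogate variable (sva 3.50.0), and each sample left out in turn. Chosen after seeing the data were fits without libraries rich in keratinocyte or muscle RNA or low in tendon genes, a sum of tendinopathy 1 and 7, muscle and synovial marker means as covariates, and halved counts. The median log2 fold change of all genes was -0.04 with TMM and -0.02 with each of the other scalings.

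The procedure was tested on simulated counts for the comparison of tendinopathy with healthy, with 17292 genes tested. It recovered 28% of 50 genes raised 2-fold, 86% of 50 raised 4-fold and 100% of 50 raised 8-fold. It recovered 28% of 50 genes with expression lowered to 0.5 of its level, of which 45 passed the filter, and made 2 false calls. The simulated genes varied independently of each other, so shared differences in tissue content between libraries were not modelled. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.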

Results

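The data were gene counts from 7 healthy hamstring tendon biopsies and 7 rotator cuff biopsies with chronic tendinopathy, a long-lasting tendon disorder. Total counts ran from 16171745 in tendinopathy 5 to 59883154 in healthy 4. Mitochondrially encoded genes took 8.65% to 51.8% of the counts, with 51.8% in healthy 4 and 40.8% in healthy 5. Body site and diagnosis changed together, so a difference between the groups covers both. In 8 of the 14 libraries both kinds of donor-sex-linked transcripts were present at 10% or more of the highest library. The p-values below assume independent libraries and would not hold as given for libraries that share RNA.

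The series asks whether signalling by AMPK, the kinase that senses low cellular energy, differs in tendinopathy. PRKAA2, the alpha-2 catalytic subunit (chromosome 1, 56645322 to 56715335, GRCh38), had a mean of 16.0 ± 19.3 CPM (SD, n = 7) in healthy tendon and 3.02 ± 2.45 CPM (SD, n = 7) in tendinopathy. PRKAG3, a gamma subunit known from skeletal muscle (chromosome 2, 218822383 to 218832086), had 11.5 ± 16.0 CPM and 0.924 ± 0.855 CPM. PRKAG2, another gamma subunit (chromosome 7, 151556111 to 151877125), had 25.2 ± 7.33 CPM and 17.3 ± 1.65 CPM. The log2 fold changes were -2.42 (SE 0.73) for PRKAA2, -3.67 (SE 1.02) for PRKAG3 and -0.54 (SE 0.16) for PRKAG2. The edgeR quasi-likelihood test gave each an adjusted p of 0.289 over all genes. Adjusted over the list alone, PRKAA2, PRKAG3 and PRKAG2 passed, each with an adjusted p of 0.0115. PRKAA1, the alpha-1 catalytic subunit, had a log2 fold change of 0.14 (SE 0.13, adjusted p = 0.672 in edgeR). The log2 fold changes of PRKAB1 (-0.19, SE 0.17), PRKAB2 (-0.59, SE 0.31, and -0.21 without healthy 3) and PRKAG1 (-0.20, SE 0.15) did not pass either adjustment.

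PRKAA2 and PRKAG3 were highest in libraries rich in skeletal muscle markers. The muscle marker mean was 11.85 log2 CPM in healthy 3, 11.69 in healthy 6 and 9.44 in healthy 2, against 8.98 in tendinopathy 5 and 2.19 in healthy 1. With that mean as a covariate, chosen after seeing the data, the log2 fold change was -0.89 (SE 0.35) for PRKAA2, -0.72 (SE 0.38) for PRKAG3 and -0.54 (SE 0.18) for PRKAG2. DESeq2 called PRKAA2 (adjusted p = 0.0210) and PRKAG3 (adjusted p = 0.0203) over all genes. As a list, the AMPK subunits ranked lower in tendinopathy by camera (6 of 7 members negative, adjusted p = 0.0350). The call was lost with an estimated correlation (adjusted p = 0.398), without healthy 2 (adjusted p = 0.0527) and without tendinopathy 3 (adjusted p = 0.0758). It was also lost with the muscle covariate (adjusted p = 0.0870), where the difference in the list mean went from -0.69 (SE 0.30) to -0.32 (SE 0.12). The other settings that lost it were the stricter low-count filter (adjusted p = 0.0654), fry (adjusted p = 0.259) and, chosen after seeing the data, the synovial covariate (adjusted p = 0.0540), the fit without healthy 1 and 2 and tendinopathy 6 (adjusted p = 0.0504) and that without healthy 2, 3 and 6 and tendinopathy 5 (adjusted p = 0.112).

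**Figure D1:**
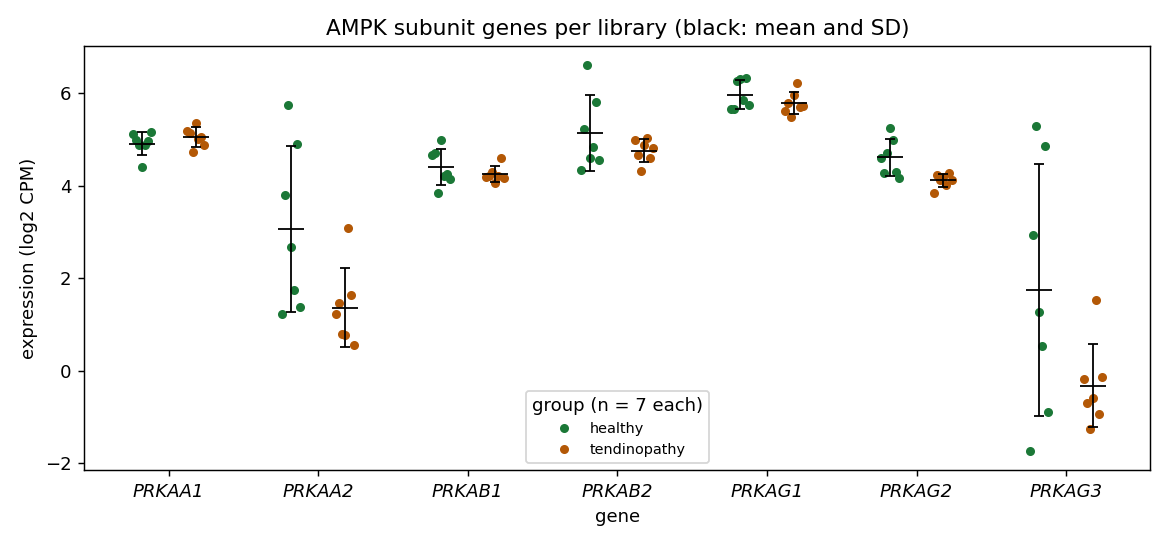
Expression of the 7 AMPK subunit genes in log2 CPM, 1 point per library and 7 libraries per group, with the mean and SD in black. PRKAA2 and PRKAG3 spread over several log2 units among healthy libraries, while PRKAA1 stayed within 4.41 to 5.36 in all libraries.

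Of the AMPK substrates and outputs, 31 were tested, and 19 had a positive and 12 a negative log2 fold change, with a median of 0.05. PPARGC1A, a coactivator that drives mitochondrial biogenesis, had a log2 fold change of -1.93 (SE 0.58). Its highest values were in healthy 3 (4.32 log2 CPM), healthy 6 (3.77) and healthy 2 (2.56), which were rich in muscle markers. Across the settings its log2 fold change ran from -2.12 to -0.48. SLC2A1, the main basal glucose transporter, had 1.09 (SE 0.42), and TXNIP, an inhibitor of thioredoxin, had -0.53 (SE 0.21). The highest SLC2A1 values were in tendinopathy 1 (6.49 log2 CPM) and tendinopathy 7 (6.32), both rich in keratinocyte markers. The other tendinopathy libraries reached 4.81, as did the healthy ones. Across the settings the log2 fold change of SLC2A1 ran from 0.23 to 1.41. Among the upstream regulators, CAMKK1, a kinase that acts on AMPK, had 1.07 (SE 0.33, and 0.66 without tendinopathy 4). PPM1A, a phosphatase, had -0.31 (SE 0.14, and -0.20 without healthy 3). STRADB had -1.29 (SE 0.42), with its highest values in healthy 6 (5.54 log2 CPM) and healthy 3 (5.41), both rich in muscle markers. Across the settings the log2 fold change of STRADB ran from -1.54 to -0.43. By edgeR, 0 of these genes passed over all genes or adjusted over the list alone, and 7 substrates and 3 regulators had an unadjusted p under 0.05. DESeq2 called 1 substrate, PPARGC1A (adjusted p = 0.0348). Camera gave an adjusted p of 0.628 for the substrates and 0.998 for the regulators. Without healthy 2, 3 and 6 and tendinopathy 5, the substrates passed as higher (median 0.19, camera adjusted p = 0.00988). That setting, chosen after seeing the data, left out the libraries richest in muscle markers.

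Across all 17546 genes, the edgeR test called 0 genes at an adjusted p of 0.05, with a lowest adjusted p of 0.289. At an unadjusted p under 0.05 there were 2375 genes, 928 higher and 1447 lower in tendinopathy, where chance gives 877.3. DESeq2 called 332 genes, 82 higher and 250 lower, and limma-voom called 0 with 1655 genes at an unadjusted p under 0.05. Among the genes with the smallest p, chosen after their values were seen, COL11A2, a cartilage collagen, had a log2 fold change of -3.92 (SE 0.78). CD70, a ligand of the TNF family, had 2.19 (SE 0.42) and PFKP, a glycolytic phosphofructokinase, 0.74 (SE 0.16). The values of the groups did not overlap in 16 genes, 8 higher and 8 lower, which is 0.0912% of genes where chance gives 0.0583%.

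Lists of collagen, proteoglycan, protease and TGF-beta response genes ranked higher in tendinopathy, while elastic fibre (camera adjusted p = 0.0592), bone (0.119) and cartilage genes (0.745) did not pass. Of 26 genes for fibrillar collagens and their assembly, 22 had a positive log2 fold change (median 0.92) and 15 an unadjusted p under 0.05. The list ranked higher by camera (adjusted p = 5.41e-08), but not with an estimated correlation (adjusted p = 0.398). COL1A1, the main tendon collagen, averaged 11.99 ± 1.41 log2 CPM (SD, n = 7) in healthy and 13.25 ± 1.68 (SD, n = 7) in tendinopathy, a log2 fold change of 1.40 (SE 0.71). COL3A1, a collagen of repair tissue, had 1.32 (SE 0.56), COL6A2 0.98 (SE 0.30) and P4HA2, a collagen prolyl hydroxylase, 0.94 (SE 0.26). LOXL4, a collagen cross-linking enzyme, went the other way at -2.79 (SE 0.71). COL6A2, P4HA2 and LOXL4 passed when adjusted over the list alone. Small proteoglycans and glycoproteins ranked higher by camera (11 of 17 positive, median 0.60, or 0.38 without tendinopathy 4, adjusted p = 0.00222), with VCAN at 1.28 (SE 0.34), BGN at 0.86 (SE 0.28) and TNXB at 1.02 (SE 0.35). With an estimated correlation the adjusted p of that list was 0.398. Matrix proteases and inhibitors did likewise (17 of 20 positive, adjusted p = 3.93e-04, and adjusted p = 0.398 with an estimated correlation). MMP14 had 0.98 (SE 0.38), MMP2 0.92 (SE 0.38) and ADAMTS14 1.78 (SE 0.78, and 0.30 to 2.09 across the settings). The TGF-beta response and myofibroblast list had 13 of 17 positive (adjusted p = 7.39e-04, and adjusted p = 0.398 with an estimated correlation), with FAP at 0.75 (SE 0.27) and TGFBI at 0.87 (SE 0.34).

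Endothelial, mast cell and senescence lists ranked higher as well. Lists that did not pass by camera included macrophage (adjusted p = 0.522), T and NK cell (0.411), erythroid (0.544), neutrophil (0.740) and adipocyte markers (0.998), heat shock and unfolded protein response (0.415) and hypoxia genes (0.750). Macrophage markers passed as higher without tendinopathy 1 and 7 (7.4e-04) and without healthy 1 and 2 and tendinopathy 6 (0.0311). They passed as lower with sample weights (0.0192) and the synovial covariate (0.00314). Synovial lining markers (0.111 in the main test) passed as higher in those leave-out settings (4.6e-04 and 0.00408). They also did so with tendinopathy 1 and 7 summed (0.0156). Of these settings, all but the weighted fit were chosen after seeing the data. Synovial lining markers passed in 7 of 32 settings, and the others left out single libraries, as fixed beforehand. All 15 endothelial markers had a positive log2 fold change (median 0.83, or 0.52 without tendinopathy 1, camera adjusted p = 1.72e-04, and adjusted p = 0.649 with an estimated correlation), with PECAM1 at 0.67 (SE 0.28), ERG at 0.63 (SE 0.26) and ROBO4 at 0.83 (SE 0.33). All 9 mast cell markers were positive (median 0.57, adjusted p = 3.69e-05, and adjusted p = 0.398 with an estimated correlation), with TPSAB1 at 0.59 (SE 0.21), TPSB2 at 0.82 (SE 0.33) and KIT at 0.63 (SE 0.25). The tryptase genes TPSAB1 and TPSB2 are near-identical and their counts are uncertain. Senescence genes were positive in 14 of 18 (adjusted p = 0.00510, and adjusted p = 0.398 with an estimated correlation), with STC1 at 1.97 (SE 0.73), CDKN1A, a cell cycle inhibitor, at 0.75 (SE 0.32) and IGFBP6 at -1.61 (SE 0.66, and -0.71 without healthy 4). Across the settings STC1 ran from 0.35 to 2.23, CDKN1A from 0.19 to 0.88 and IGFBP6 from -1.88 to -0.0868. Tendinopathy 1 and 7 had keratinocyte marker means of 8.15 and 8.01 log2 CPM, and the highest collagen list means (8.98 and 8.85). Without both libraries, chosen after seeing the data, 8 lists ranked higher instead of 13, with the macrophage and synovial lining lists newly among them. The endothelial, TGF-beta and senescence lists no longer passed (adjusted p = 0.135, 0.0824 and 0.0597 by camera). Neither did the mural, fibroblast progenitor, cytokine, B and plasma cell and AMPK-related kinase lists (0.135, 0.0824, 0.127, 0.0742 and 0.565). Immediate early genes turned to a median of -0.20 and did not pass (0.138).

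Camera also called the lists of mural cells, fibroblast progenitors, cytokines, immediate early genes, B and plasma cells and AMPK-related kinases as higher. PDGFRB (1.02, SE 0.33), NOTCH3 (1.24, SE 0.43) and CSPG4 (0.57, SE 0.20) led the mural markers, and CD248 (0.85, SE 0.26), DPT (0.90, SE 0.33) and CLEC3B (0.72, SE 0.26) the progenitor markers. TNFAIP6 (0.97, SE 0.28), LIF (0.78, SE 0.35) and PTGES (0.34, SE 0.17, and 0.21 without tendinopathy 3) led the cytokines. EGR3 (0.88, SE 0.25), FOSL2 (1.05, SE 0.39) and FOSL1 (1.17, SE 0.53, and 0.74 without tendinopathy 1) led the immediate early genes. CD79B had 1.53 (SE 0.50, and 0.86 without tendinopathy 4), JCHAIN 0.34 (SE 0.76) and MZB1 0.29 (SE 0.73). On leaving out single libraries, JCHAIN ran from 0.13 to 0.88 and MZB1 from 0.07 to 1.04. SIK3 had 0.46 (SE 0.18), NUAK2 0.90 (SE 0.42, and 0.56 without tendinopathy 1) and MARK1 0.26 (SE 0.16). With an estimated correlation none of these lists passed, with adjusted p of 0.649 for mural, 0.398 for progenitor and cytokine, 0.795 for immediate early, 0.717 for B cell and 0.649 for kinase genes. Each call was also lost on leaving out single libraries. The highest camera adjusted p was 0.219, 0.0950 and 0.268 for mural, progenitor and B cell genes without healthy 1, 0.103 for cytokines without healthy 4, and 0.611 and 0.141 for immediate early and kinase genes without tendinopathy 1.

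**Figure D2:**
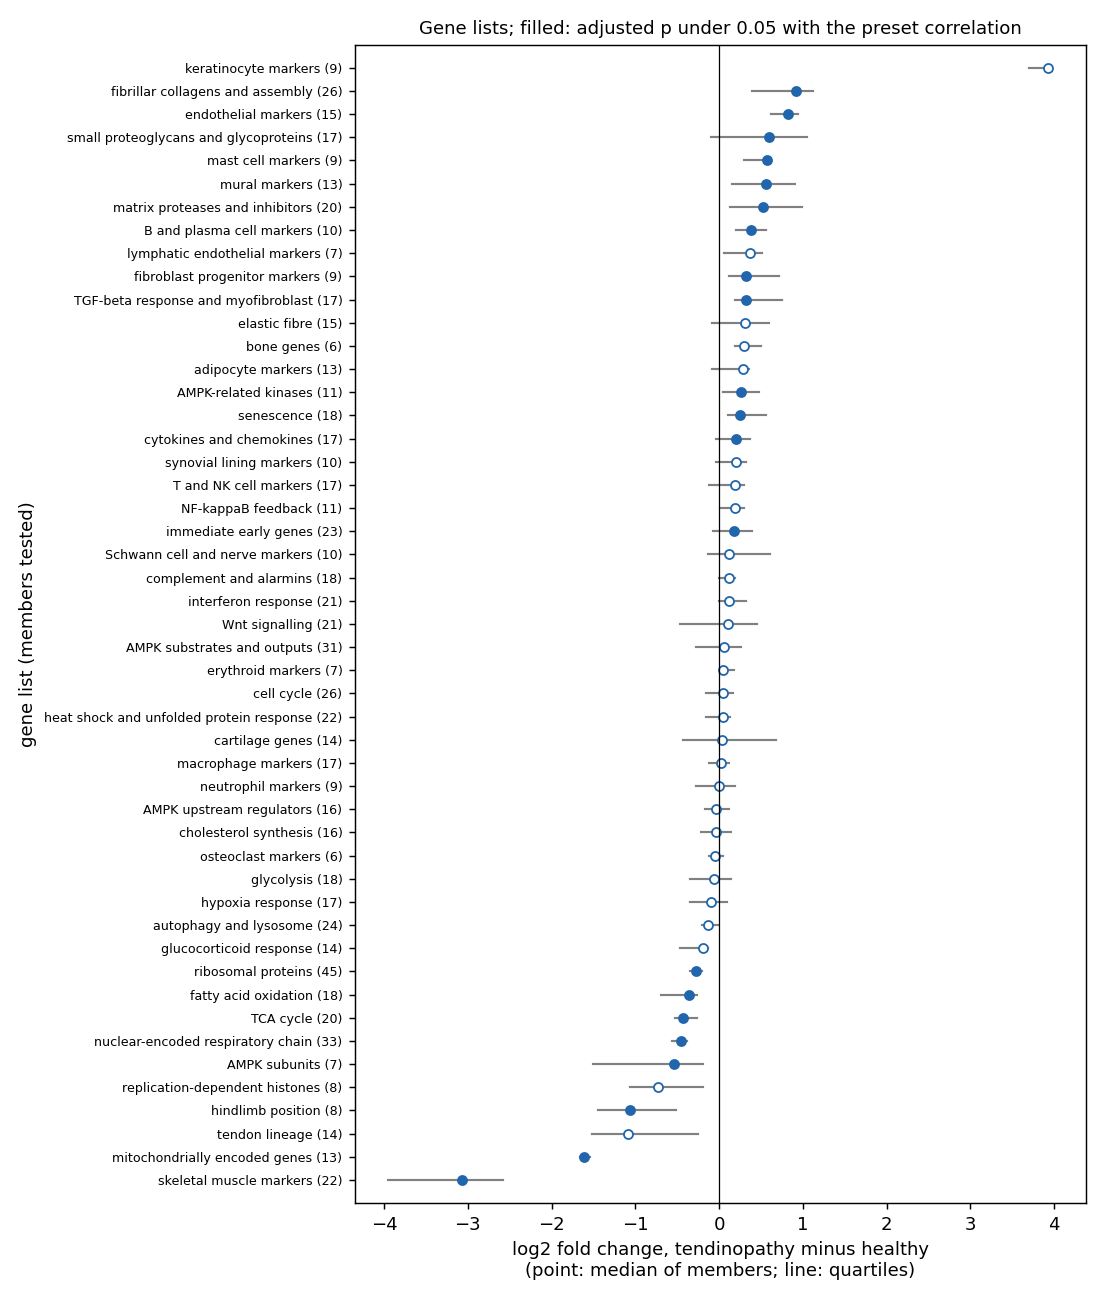
Median log2 fold change (tendinopathy minus healthy) of the tested members of each gene list, with a line from the lower to the upper quartile and filled points for an adjusted p under 0.05 by camera with a preset correlation. The 13 higher and 8 lower lists are filled, and 0 lists passed with an estimated correlation.

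Lists of skeletal muscle, respiratory chain, fatty acid oxidation, TCA cycle and mitochondrially encoded genes ranked lower in tendinopathy, while the glycolysis list did not pass (median -0.07, camera adjusted p = 0.716). All 22 skeletal muscle markers had a negative log2 fold change (median -3.07), with MYH1, a fast myosin, at -4.78 (SE 1.32), MYBPC2 at -4.28 (SE 1.19) and TNNT3 at -3.95 (SE 1.15). The list ranked lower by camera (adjusted p = 4.42e-05), but not with an estimated correlation (adjusted p = 0.649), and 13 members passed when adjusted over the list alone. All 33 nuclear genes of the respiratory chain were negative (median -0.46, or -0.28 without healthy 3, adjusted p = 4.73e-06, and adjusted p = 0.649 with an estimated correlation), with NDUFA10 at -0.45 (SE 0.19), UQCRC2 at -0.50 (SE 0.21) and NDUFS1 at -0.40 (SE 0.19). All 18 fatty acid oxidation genes were negative (median -0.36, adjusted p = 6.95e-06, and adjusted p = 0.398 with an estimated correlation), with ACADM at -0.78 (SE 0.24), ETFDH at -0.76 (SE 0.28) and HADHA at -0.30 (SE 0.12). The TCA cycle list had 18 of 20 negative (adjusted p = 1.72e-04, and adjusted p = 0.649 with an estimated correlation), with PDHA1 at -0.70 (SE 0.28), FH at -0.51 (SE 0.22) and IDH2 at -1.40 (SE 0.62, and -0.80 without healthy 6). All 13 mitochondrially encoded genes were negative (median -1.61, or -0.98 without healthy 4, adjusted p = 1.72e-07, and adjusted p = 0.398 with an estimated correlation), with MT-ATP8 at -1.88 (SE 0.51), MT-ND4L at -1.54 (SE 0.48, and -0.94 without healthy 4) and MT-CO1 at -1.84 (SE 0.58). The mean of these genes was 15.43 log2 CPM in healthy 4 and 14.57 in healthy 5, against at most 12.27 in healthy 1, 6 and 7 and 11.80 to 13.20 in tendinopathy. Ribosomal protein genes were negative in 43 of 45 (median -0.27, or -0.0446 without healthy 4, adjusted p = 1.72e-04), including RPL22 at -0.52 (SE 0.19), RPS25 at -0.58 (SE 0.26) and RPL38 at -0.44 (SE 0.22). The ribosomal call was lost with an estimated correlation (adjusted p = 0.765) and without healthy 4 (adjusted p = 0.307). It was also lost with sample weights (median -0.0734, camera adjusted p = 0.149) and with fry (adjusted p = 0.633). Without healthy 2, 3 and 6 and tendinopathy 5, the libraries richest in muscle markers, the muscle, TCA cycle and AMPK subunit lists no longer passed (camera adjusted p = 0.762, 0.126 and 0.112). With the muscle covariate the respiratory chain list no longer passed (adjusted p = 0.156), and the difference in its mean went from -0.37 (SE 0.28) to -0.0692 (SE 0.17). By camera with the preset correlation, the TCA cycle, fatty acid oxidation and mitochondrially encoded lists still passed with that covariate. The respiratory chain, fatty acid oxidation and mitochondrially encoded lists still passed without the libraries richest in muscle markers. Both settings were chosen after seeing the data.

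**Figure D3:**
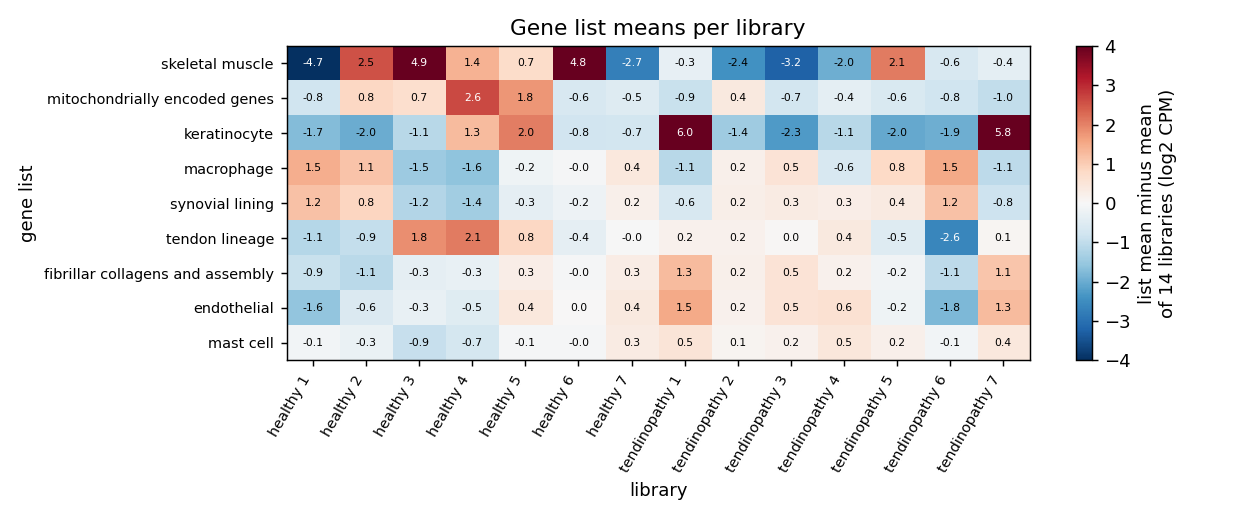
Mean log2 CPM of 9 gene lists in each of the 14 libraries, minus the mean of all 14 libraries, as number and as colour, which is limited at 4 in both directions. Skeletal muscle genes stand out in healthy 3 and 6, keratinocyte genes in tendinopathy 1 and 7, and macrophage genes in healthy 1 and tendinopathy 6.

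Tendon and limb position genes varied widely within the groups. TNMD, a tendon membrane protein, had a log2 fold change of -3.08 (SE 0.90), MKX, a tendon transcription factor, -1.58 (SE 0.74) and SCX, another, -1.05 (SE 0.73, and -0.57 without healthy 5), and none passed in edgeR (adjusted p = 0.289, 0.367 and 0.537). DESeq2 called TNMD (adjusted p = 0.0316). Of 14 tendon lineage genes, 11 were negative (camera adjusted p = 0.151). The list passed in 5 of 32 settings. It ranked lower with no low-count filter (camera adjusted p = 0.0159) and with 1 surrogate variable (0.0281). It also did so without healthy 1 and 2 and tendinopathy 6 (0.00581) and without tendinopathy 1 and 7 (0.0426), both chosen after seeing the data. With sample weights its median turned to 0.0594. The hindlimb position list ranked lower in tendinopathy by camera (7 of 8 negative, adjusted p = 7.18e-04), and not with an estimated correlation (adjusted p = 0.365). HOXC10 had -1.44 (SE 0.30), HOXC9 -1.57 (SE 0.35) and HOXC8 -1.46 (SE 0.48), and these 3 and HOXC11 passed when adjusted over the list alone. PITX1 and TBX4, hindlimb transcription factors, had -1.02 (SE 0.52) and -0.64 (SE 0.46), and TBX5, the forelimb factor, had 0.96 (SE 0.35). HOXC10 minus TBX5 was 3.06 in tendinopathy 6, outside the 0.38 to 1.62 of the other 6 tendinopathy libraries and inside the 1.88 to 6.14 of the healthy libraries.

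**Figure D4:**
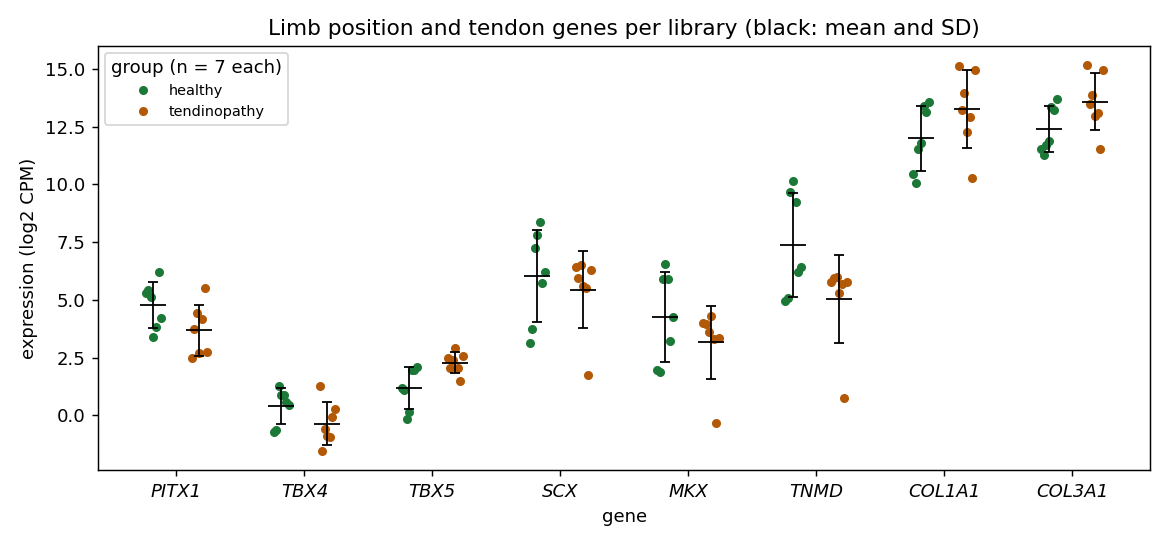
Expression of 3 limb position genes and 5 tendon genes in log2 CPM, 1 point per library and 7 libraries per group, with the mean and SD in black. In tendinopathy 6, SCX (1.76), MKX (-0.32) and TNMD (0.73) lay below every other tendinopathy library.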

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

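The tests on keratinocyte genes, on the means of metabolic lists and on limb position genes were chosen only after the result was seen. Among 170 groups of 7 values, 14 had a value far from the rest, where chance gives about 8.5 (1 in 20).

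Among the tendinopathy libraries, tendinopathy 6 lay apart at the low end in 5 genes. These were SCX at 1.76 log2 CPM, MKX at -0.32, TNMD at 0.73, JCHAIN at -1.55 and DPT at 6.47. It lay at the high end of its group in PRKAB1 (4.60). Within the same group, tendinopathy 5 was highest in PRKAA2 (3.08), PRKAG3 (1.53), STRADB (3.77) and in the muscle marker mean (8.98). Of the tendinopathy libraries, tendinopathy 2 was highest in MT-ATP8 (9.98), MT-CO1 (14.66) and in the mitochondrial share of counts (24.2%). Tendinopathy 3 was highest in PTGES (4.71), and healthy 4 was lowest in PRKAA1 (4.41).

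HOXC10 minus TBX5 in tendinopathy 6 was 3.06, where the other 6 tendinopathy libraries reached 1.62 and the healthy libraries began at 1.88. The title of this library carried the prefix of the healthy titles, and its column name that of the tendinopathy columns. The number in its title differed from that in its column name as well. Titles and column names also differed for tendinopathy 1, tendinopathy 7 and healthy 2, in the number but not in the prefix. A wrong label on tendinopathy 6, or RNA of a hamstring library mixed into it, could give the value of 3.06. Its other limb position values were mixed. The hindlimb list mean (1.70) lay inside the range of the other tendinopathy libraries (1.48 to 1.78) and of the healthy ones (1.54 to 3.04). PITX1 (5.49) lay above the other tendinopathy libraries, whereas HOXC9 (2.11) lay below every healthy library (lowest 2.12). SCX, MKX and TNMD also lay below every healthy library (lowest 3.14, 1.87 and 4.93). By chi-square per degree of freedom, healthy 1 and tendinopathy 6 were the second closest pair of libraries (21.3) and healthy 7 and tendinopathy 3, also from different groups, the third (38.9). Without tendinopathy 6, edgeR still called 0 genes (2786 at an unadjusted p under 0.05), and a biopsy that held little tendon remains open as untested.

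Keratinocyte genes were high in tendinopathy 1 and 7 and recurred in healthy 5 at a median of 4.79% of their level (SD of the log2 ratios 0.21 over 9 genes) and in healthy 4 at 1.70% (SD 0.43), where the SD of the other libraries reached 2.21. For macrophage genes, healthy 2 held a median of 63.6% of the level in healthy 1 and tendinopathy 6, with an SD of 0.0367 over 17 genes; of the 12 libraries outside that pair, 5 had an SD under 0.25, and the highest was 0.58. In all, 8 of 14 libraries held both kinds of donor-sex-linked transcripts at 10% or more of the highest library, which a single donor would not give, so RNA or reads of several donors may have been mixed. Mixed libraries are not independent, so the p-values and list calls would then not hold as given. An equal carry-over of reads into every library is argued against by a 27.0-fold span of the median keratinocyte ratio among the other 12 libraries, and no biological explanation was tested.

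The lower PRKAA2 and PRKAG3 of tendinopathy may come from skeletal muscle RNA in some healthy biopsies: with the muscle marker mean as a covariate, at most 36.9% of either log2 fold change was kept. Of the differences in list means, the respiratory chain kept 18.6% (-0.0692, SE 0.17) and the TCA cycle 34.0% (-0.11, SE 0.12), which muscle RNA may likewise explain. For PRKAG2, muscle RNA as the whole cause is argued against, since 100.1% of its log2 fold change was kept. For fatty acid oxidation the share kept was 52.0%, and for mitochondrially encoded genes 87.8%, both within 1 SE of the bound, so muscle and the diagnosis cannot be told apart there. Tendinopathy itself and the body site remain open as untested explanations, because the design joins them.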

How the results depend on the processing

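Settings added after seeing the data were those without named sets of libraries, the summed pair, both marker covariates and halved counts. The edgeR and limma settings called 0 genes in every run (from 1085 to 7491 genes at an unadjusted p under 0.05), as in the main test (2375), and DESeq2 differed. DESeq2 called 82 genes higher and 250 lower, 59 and 243 of them at least 2-fold, with 2 AMPK subunits and 1 AMPK substrate; the cause was not tested. Of the lists, 13 ranked higher and 8 lower. With an estimated correlation and with fry it was 0 and 0; the cause was not tested. Lists ranked higher numbered 7 with no low-count filter and 8 without tendinopathy 1 and 7, and lists ranked lower numbered 5 both without healthy 2, 3 and 6 and tendinopathy 5 and with the muscle covariate; the cause was not tested. Directions reversed as follows, and the cause was not tested. With sample weights, SCX was 0.0216, and the list medians were -0.0379 for AMPK substrates, 0.0594 for tendon lineage, -0.365 for macrophage (adjusted p = 0.0192) and -0.0092 for synovial lining. Without tendinopathy 1 and 7, the medians were -0.0325 for AMPK substrates, -0.20 for immediate early genes and -2.10 for keratinocyte markers (camera adjusted p = 7.4e-04), which those libraries held. Without healthy 2, 3 and 6 and tendinopathy 5, PRKAB2 was 0.14, IDH2 0.0149, JCHAIN -0.14 and MZB1 -0.36, and the medians were 0.0401 for AMPK upstream regulators and -0.18 for macrophage. With the muscle covariate, the medians were 0.0283 for AMPK upstream regulators, 0.0314 for skeletal muscle and -0.0856 for macrophage. With the synovial covariate they were 0.0373 for AMPK upstream regulators and -0.11 for macrophage. Leaving out single libraries moved the median of AMPK substrates between -0.0557 and 0.14, of AMPK upstream regulators between -0.0586 and 0.0341 and of macrophage markers between -0.28 and 0.31. Leaving out single libraries moved 20 of 81 named genes by over 1.5 times. The other genes taken by the naming rule, and the other lists followed across the settings, kept their direction. The direction of lists such as glycolysis, cartilage, bone, elastic fibre, hypoxia and T and NK cell markers was not followed across the settings. No paired analysis was possible because the replicate numbers were given in accession order. Simulation recovered 28% of 2-fold changes at this size, so smaller differences could not be seen reliably. It did not model shared differences in tissue content between libraries, so its recovery of larger changes may not hold here. MYH1, at a log2 fold change of -4.78, was not called by edgeR in the main test.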

Other observations

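The tests of other splits were fixed before their results were seen. Some biology outside the comparisons above stood out as values. Macrophage markers averaged 8.74 log2 CPM in healthy 1 and 8.79 in tendinopathy 6, against 5.67 in healthy 4. Erythroid markers ran from -0.04 in tendinopathy 6 to 5.56 in tendinopathy 3, and B and plasma cell markers from -1.55 in healthy 1 to 2.71 in healthy 7. Keratinocyte markers passed in 9 of 9 genes when adjusted over the list alone, with KRT5 at a log2 fold change of 4.07 and KRT14 at 3.98, and tendinopathy 1 and 7 held them. As a list they did not pass by camera (adjusted p = 0.187). They passed as higher with 1 surrogate variable (0.00248) and the synovial covariate (6.3e-06). Without tendinopathy 1 and 7 they passed as lower (median -2.10, 7.4e-04). COL11A2 (-3.92) and CHAD (-3.32), both cartilage genes, passed when adjusted over the cartilage list alone, while the list median was 0.03.

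The 14 libraries were also split at random into groups of 7 and 7, with 100 of the 1716 splits taken, the real one included in each count below. By edgeR the real split gave 0 genes, which all 100 reach by construction, so that count decides nothing about chance; the highest of the others gave 717. For genes at an unadjusted p under 0.05, 12 of the 100 splits gave as many as the real 2375, and the highest of the others gave 4136. For gene lists past the threshold with a preset correlation, 21 of the 100 splits gave as many as the real 21, and the highest of the others gave 31. For DESeq2, run on the filtered genes, 4 of 25 splits, the real one among them, gave as many as the real 295, and the highest of the others gave 1106. Chance could thus not be excluded for the counts at an unadjusted p under 0.05, of lists and by DESeq2. The DESeq2 split with 1106 genes, several times the real 295, points to a structure of the samples other than the groups.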
